A study of Homo sapiens with 20 samples.

How the data were processed

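Small RNA of 2 human cell lines was sequenced in 20 libraries, per the labels. HCT116 is a colon cancer line and HEK293E a line derived from human embryonic kidney cells. DROSHA, the nuclease that cuts microRNA (miRNA) hairpins out of primary transcripts in the nucleus, had been knocked out in cells of both lines. The knockout cells were rescued with full-length DROSHA or with DROSHA-p140, a shorter form, in 3 libraries each per line. A single library came from untreated wild-type HCT116 cells and a single one from HCT116 knockout cells given GFP. Wild-type HCT116 cells were also kept for 72 hr in medium with 9.1% or 0.1% fetal bovine serum (FBS), with 3 libraries each. Groups and replicate numbers were taken from the sample titles.

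Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase, mixed with equimolar spike-in RNAs, size-selected on a denaturing gel, ligated to randomized adaptors at both ends and sequenced on a MiSeq. Per the submitters' processing notes, cutadapt, STAR and bedtools were used with the hg38 genome. Their versions, the miRNA annotation release, the rule for reads that map to several places and any use of the random adaptor bases are not given in the sources used here. The deposited values are whole-number read counts per mature miRNA and hairpin, not normalized. Each table held 2813 values for 2588 mature miRNAs of 1881 hairpins, and 0 values named anything other than a miRNA, so no spike-in could be used for scaling. Scaling to the spike-in RNAs, planned as an alternative, was therefore not run.

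A total of 167 mature miRNAs were listed under more than 1 hairpin. Of the 39 such miRNAs with at least 500 reads, 31 had a lowest copy above 95% of the highest, which is what counting the same reads at each copy gives. The copy with the highest total was therefore kept for each mature miRNA. Values of miRNAs with several copies cannot be assigned to 1 hairpin, and the copies of miR-194-5p and miR-219a-5p were unequal. After this step the libraries held between 38288 reads (knockout with GFP) and 2822317 reads (0.1% FBS, replicate 3). The HCT116 libraries held 764014 to 873717 reads with full-length DROSHA and 305603 to 327011 with p140. The HEK293E libraries held 224262 to 335803 reads with full-length DROSHA and 135085 to 246008 with p140. The untreated wild-type library held 856658 reads, and the libraries of the serum experiment 1745625 to 2822317.

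Replicates were compared before they were averaged, and no 2 libraries were identical. The chi-square per degree of freedom between replicates of a group lay between 4.32 and 114, so every pair differed by more than counting noise. Replicate 3 stood apart in the HCT116 knockout groups. The value for full-length replicates 1 and 2 was 4.32, against 48.7 and 46.1 for their comparisons with replicate 3. With p140 the value for replicates 1 and 2 was 5.65, against 114 and 89.4 with replicate 3. Replicate 3 stood apart in the serum experiment too, with 10.2 for replicates 1 and 2 in 0.1% FBS against 70.5 and 89.6 with replicate 3, and 9.65 in 9.1% FBS against 84.6 and 57.7. The labels do not say whether replicates came from separate cultures, so all p-values measure only the spread between these samples, which may be technical. Sequencing reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

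Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, low counts removed with filterByExpr at a minimum count of 10, Benjamini-Hochberg adjustment, threshold 0.05). Each line and the serum experiment were fitted alone, with 446 miRNAs tested in HCT116, 416 in HEK293E and 577 in the serum experiment. The difference in p140 effect between the lines was tested as the interaction of line and DROSHA form over 12 libraries, with 515 miRNAs tested, of which 105 had an unadjusted p under 0.05. Levels are CPM (counts scaled to a common library total), TMM-scaled where a test is given, as mean ± SD over n = 3 libraries, and log2 fold changes are given ± standard error. All tests were two-sided.

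Hairpins were placed on GENCODE 29 gene models of hg38, with coordinates counted from 1. All 1881 lay within a miRNA gene of that annotation. A hairpin inside a gene on the same strand that touched no exon was called intronic (952), one overlapping only exons exonic (155), one with no host gene intergenic (610), and one that was intronic in some transcripts and exonic in others mixed (164). Intronic miRNAs were compared with exonic and intergenic ones pooled. Mixed hairpins, miRNAs whose copies fell in different classes and the list of DROSHA-independent miRNAs were left out of both. The comparison used the difference of median log2 fold changes, limma 3.58.1's camera test with a preset correlation of 0.01 and with an estimated one, and a permutation of class labels over loci (hairpins within 10 kb on 1 strand counted as 1, 100000 resamples). The intronic and other miRNAs numbered 245 and 109 in HCT116 (143 and 72 loci), 222 and 108 in HEK293E (132 and 76 loci), and 336 and 142 in the serum experiment. Among the miRNAs tested in both lines 192 were intronic and 86 exonic or intergenic. Host intron lengths came from the same gene models, as the shortest same-strand intron of any transcript that held the mature miRNA.

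A total of 19 lists of miRNA families, clusters and cell type markers, the conservation list and the rule for named miRNAs were fixed before the data were examined. The rule took, per comparison, the 12 largest rises and 12 largest falls among miRNAs at an adjusted p under 0.05, with a mean of at least 100 CPM and no overlap between the replicates of the groups. It also took the most abundant members of each list (2 to 4 as planned, up to 2 as applied), the 5 most abundant miRNAs, and miR-320a, miR-484 and miR-877-5p. For the comparison of wild type with knockout it took the 10 largest rises and falls in CPM ratio among miRNAs with at least 100 reads in either library. miRNAs named outside the rule were chosen after their values were seen. Wild type and knockout with GFP have 1 library each, so their values carry exact Poisson intervals at 95% and no test. Of 194 miRNAs with at least 100 reads in either, 181 were called DROSHA-dependent. The miRNAs called both with p140 in HCT116 and after starvation numbered 105. Of the 115 rises of more than 2-fold in HCT116, 101 were outside the DROSHA-independent list. A count of 0 was read as at most 3 reads per library. Lists were placed among 10000 random lists of the same size matched on mean expression.

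Whether replicate numbers pair the libraries was checked from the correlation of deviations from the group means. It was 0.47, 0.36 and 0.68 for replicates 1 to 3 of HCT116, 0.56, 0.35 and 0.37 for HEK293E, and 0.26, 0.15 and 0.67 in the serum experiment. All exceeded 0.1, so a fit with the replicate number as a block is printed where it changes a call. The highest correlation between different numbers was 0.37 in HCT116, 0.15 in HEK293E and 0.48 in the serum experiment, all but that of HEK293E above the lowest for a shared number, so the pairing of replicates 1 and 2 is weak in HCT116 and the serum experiment. The numbers come from the labels, which do not say what they mark.

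The scripts were tested on simulated counts with the real means and library sizes, in which 67, 67 and 66 miRNAs were changed 1.5-fold, 2-fold and 4-fold. In the HCT116 design (432 miRNAs tested) 16.7% of the 1.5-fold, 57.1% of the 2-fold and 96.8% of the 4-fold changes were called. In the HEK293E design (407 tested) the shares were 35.4%, 71.6% and 96.9%. In the serum design (568 tested) they were 44.6%, 93.9% and 98.5%. The interaction (479 tested) recovered 6.45%, 16.7% and 61.3%, so differences between the lines of less than 4-fold were mostly missed.

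The alternatives tried were RLE scaling, scaling to the DROSHA-independent list, DESeq2 1.42.0, limma-voom, no count filter, a mean of at least 100 CPM, a joint fit of all replicated libraries, the replicate block, copies summed, 1 arm per hairpin, other hairpin classes, and each library left out in turn. Counts that equal a miRNA number in the fixed lists are rounded to 2 digits in the sensitivity part. In full they were 216 calls in HEK293E on the DROSHA-independent scale, 141 in HCT116 at a mean of at least 100 CPM, and 183, 326 and 367 with the replicate block in HEK293E, HCT116 and the serum experiment. With 1 library left out the lowest were 184 in HCT116 and 205 in the serum experiment, and the highest in HEK293E was 129. Chosen after seeing the data were the estimated correlation for the conservation comparison, the restriction to DROSHA-dependent miRNAs, classes from basic transcripts only, summed copies, leaving out replicate 3 of both HCT116 groups, and DROSHA-independent scaling of the interaction. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.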

Results

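The deposited counts cover mature miRNAs in 20 small RNA libraries of HCT116 and HEK293E cells. They allow 3 replicated comparisons with n = 3 libraries per group, namely p140 against full-length DROSHA in knockout HCT116 cells, the same in knockout HEK293E cells, and 0.1% against 9.1% FBS in wild-type HCT116 cells. The untreated wild-type and knockout with GFP libraries have no replicates and are compared by description only, for miRNAs with enough reads. They cannot separate the loss of DROSHA from other differences between the cell populations. The series title names the role of DROSHA's proline-rich disordered domain in the processing of miRNAs that lie in introns. Reads per library ranged from 38288 to 2822317.

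Canonical miRNAs were far lower in the knockout with GFP than in wild type, and miRNAs made without DROSHA took most of its reads. The most abundant miRNA of HCT116 cells, the oncogenic miR-21-5p, had 324564 of 856658 reads in untreated wild type. In the knockout with GFP it had 2026 of 38288, so part of this gap in reads is depth. miR-320a, whose precursor is cut without DROSHA, had 11889 CPM in wild type (interval 11659 to 12122) and 611575 CPM in the knockout (603767 to 619460), and alone took 61.2% of the knockout's reads. The DROSHA-independent list (mirtrons, which are excised by splicing, and the capped or terminal hairpins miR-320a and miR-484) held 1.27% of reads in wild type (exact Clopper-Pearson interval 1.24 to 1.29) and 69.7% in the knockout (69.3 to 70.2). DROSHA's own transcript is not measured by these counts, so this list is the check of the knockout label, and it goes with the label. There is 1 library of each kind, hence no replicate check.

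Of the miRNAs with at least 100 reads in either library, all but 13 were over 16-fold lower in the knockout when both libraries were scaled to the DROSHA-independent list, with a median of 325.7-fold (313-fold with the 21 miRNAs at 0 reads set to 3). These are called DROSHA-dependent here. Among them miR-21-5p was 394-fold lower, let-7a-5p 359-fold, miR-374a-5p 366-fold, miR-222-3p 328.4-fold and the epithelial miR-200c-3p 535-fold. The 13 others had list-scaled log2 ratios between -0.45 and 2.96. This scale takes the output of the list, mostly miR-320a, as unchanged, so miR-320a lies near 0 by construction. Folds in CPM were smaller, as for miR-200b-3p, 15.6-fold lower in CPM and 820-fold on the list's scale. In CPM the highest ratios of knockout to wild type were those of the mirtrons miR-1229-3p (457-fold, interval 216.2 to 1157), miR-1226-3p (210-fold), miR-877-3p (182.5-fold) and miR-877-5p (175-fold). They were followed by miR-7706 (131-fold), miR-484 (76.7-fold), miR-3615 (73.8-fold), miR-320d (60.6-fold), miR-1260b (54.2-fold) and miR-320c (52.2-fold). miR-320a (51.4-fold), miR-320b (42.4-fold) and miR-4521 (40.4-fold) complete the 13. Expressed miRNAs absent from the knockout could only be bounded at its depth. miR-361-5p was at least 7.54-fold lower in CPM, miR-96-5p at least 5.96-fold, miR-335-5p at least 4.68-fold and miR-660-5p at least 4.50-fold. For miR-132-3p, miR-1296-5p, miR-361-3p, miR-193b-3p, miR-33b-5p and miR-339-3p the bounds lay between 3.78-fold and 2.31-fold.

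**Figure D1:**
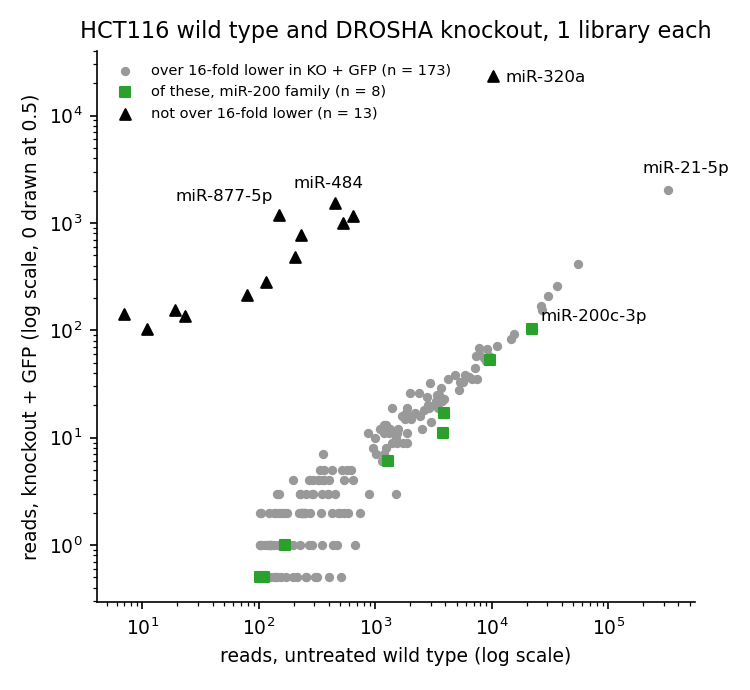
Reads of each miRNA with at least 100 in either library in the untreated wild-type library (horizontal, log scale) and in the knockout with GFP (vertical, log scale, 0 drawn at 0.5), 1 library each. The 13 miRNAs drawn as triangles lie above the DROSHA-dependent ones, of which the 8 of the miR-200 family are squares.

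Among the fixed lists with members in this comparison, the DROSHA-independent list had a median log2 ratio of knockout to wild type of 7.48 in CPM and stood at percentile 100 of random lists. The miR-200 list was lowest, with a median of -3.20 at percentile 0.25. The medians of the other lists were -2.54 for let-7 (percentile 17.4), -2.57 for miR-17/92 (20.0), -2.31 for miR-106b/25 (70.1), -1.58 for the p53-linked list (43.1) and -2.26 for miR-15/16 (27.3). They were -2.67 for miR-23/27/24 (23.1), -2.67 for miR-29/30 (22.7), -2.45 for miR-221 and miR-222 (65.6), -2.22 for the HOX loci (56.9) and -2.05 for the CLCN5 cluster (5.91). These percentiles describe the 2 libraries only.

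The DROSHA-independent share of reads was lower in all rescued libraries than in the knockout with GFP, and higher with p140 than with full-length DROSHA in each line, without overlap of the replicates. In HCT116 it was 4.09% ± 1.19 (SD, n = 3) with full-length DROSHA and 15.7% ± 7.55 with p140. The p140 replicates held 21.04%, 18.9% and 7.05%, so replicate 3 lay nearer to the full-length libraries, and the difference of 11.6 percentage points became 15.2 without the replicates numbered 3. In HEK293E the share was 11.3% ± 0.88 with full-length DROSHA and 17.7% ± 2.27 with p140. It was 0.99% ± 0.18 in 9.1% FBS and 1.18% ± 0.23 in 0.1% FBS. miR-320a in CPM stood at 292% of its untreated wild-type level with full-length DROSHA and at 1124% with p140.

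**Figure D2:**
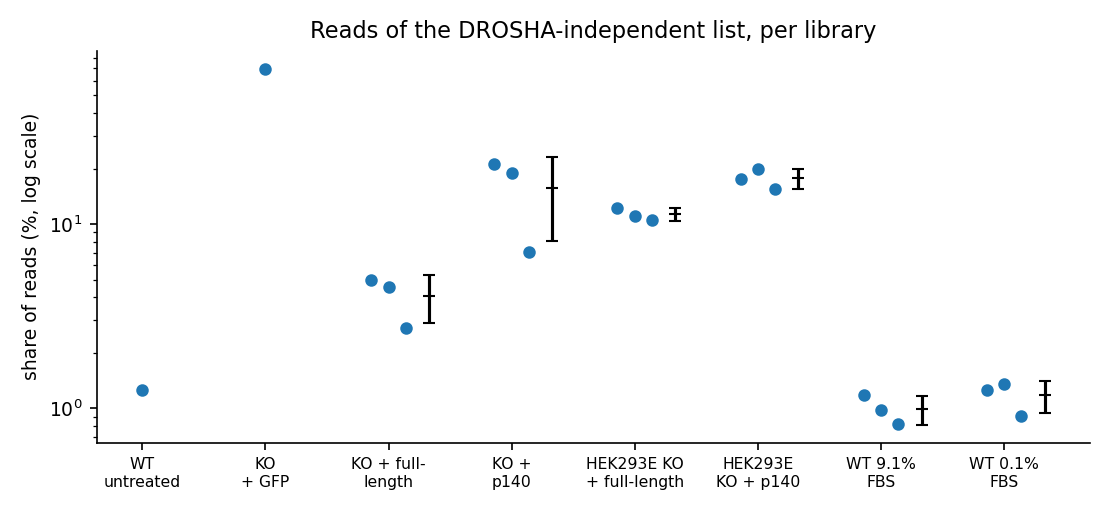
Share of reads from the DROSHA-independent list (percent, log scale) in each of the 20 libraries, with mean ± SD where a group has 3. The share runs from 0.82% in a library of the 9.1% FBS group to 69.7% in the knockout with GFP, and the p140 libraries of each line lie above their full-length counterparts.

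The first comparison asks what HCT116 cells lose when p140 replaces full-length DROSHA. Intronic miRNAs fell most. miR-1296-5p (intron of JMJD1C, chr10:63373012-63373033) had 406 ± 26.3 CPM with full-length DROSHA and 19.5 ± 8.44 with p140, a log2 fold change of -4.36 ± 0.32. miR-374a-5p (intron of the noncoding gene FTX, chrX:74287325-74287346) fell from 3879 ± 151.2 to 350.2 ± 80.4 CPM. Mirtrons and other miRNAs made without DROSHA rose about 4-fold, among them miR-877-5p (intron of ABCF1, chr6:30584332-30584351), from 1635 ± 569 to 6967 ± 3740 CPM. Of 446 miRNAs tested, 266 changed at an adjusted p under 0.05 with edgeR's quasi-likelihood test, and 52.3% of the changes were falls. Of the rises 115 were of more than 2-fold. Replicates of the groups did not overlap for 64.8% of the miRNAs, against 10% by chance.

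The 12 largest falls, under the rule of at least 100 CPM and no overlap, were in introns with 1 exception. miR-421 fell by 4.16 on the log2 scale and miR-374b-5p by 3.62, both within FTX. miR-629-5p (TLE3) fell by 4.12, miR-1301-3p (DNMT3A) by 3.42, miR-625-3p (FUT8) by 2.96, miR-454-3p (SKA2) by 2.87, miR-551a (MEGF6) by 2.81 and miR-590-5p (EIF4H) by 2.70. miR-196a-5p fell by 2.87. The exception was the intergenic miR-345-5p, which fell by 2.94. Adjusted p-values of these 12 ranged from 5.0e-05 for miR-374a-5p to 0.0035 for miR-590-5p (edgeR's quasi-likelihood test, Benjamini-Hochberg). miR-21-5p (chr17:59841273-59841294, exonic in VMP1), the most abundant of all, fell by 0.83 ± 0.11, from 373158 ± 22643 to 209941 ± 22313 CPM.

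The 12 largest rises at a mean of at least 100 CPM without overlap between the groups were of similar size. miR-4521 (intergenic, chr17:8186948-8186969) rose by 2.18 ± 0.30 on the log2 scale, from 1972 ± 20.4 to 8918 ± 3634 CPM. miR-1224-5p (VWA5B2) rose by 2.12, miR-1275 by 2.11, miR-4286 by 2.11, miR-877-5p by 2.09, miR-6886-5p by 2.08 and miR-1260b by 2.02. miR-636 (SRSF2) rose by 2.01, miR-1254 by 1.98, miR-3620-3p (ARF1) by 1.91, miR-320a (intergenic, chr8:22244975-22244996) by 1.90 and miR-1229-3p (MGAT4B) by 1.89. Their adjusted p-values lay between 9.2e-04 (miR-1260b) and 0.011 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The 14 tested members of the DROSHA-independent list all rose, also when adjusted over the list alone (14), with a median of 1.87 (camera, adjusted p = 9.3e-06 over 12 lists, and adjusted p = 0.90 with an estimated correlation). miR-484 (exonic in NDE1) was among them, at 1.70 ± 0.23. On a scale set by that list its median is near 0 by construction (-0.03), the median of all miRNAs shifts by -1.62, and the calls become 170 falls and 0 rises, against 52.3% falls on the main scale. Every direction given here is therefore relative to the bulk of the miRNA reads.

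Intronic miRNAs were lower than exonic and intergenic ones with p140. Their median log2 fold change was -0.54 (245 miRNAs, quartiles -1.45 and 0.29) against 0.30 (109 miRNAs, quartiles -0.33 and 1.27), a difference of -0.83. Among intronic miRNAs 109 fell and 48 rose, and among the others 18 fell and 34 rose. The median of the others was 0.09 with DESeq2 and -1.27 on the DROSHA-independent scale, with -0.76 and -2.14 for the intronic ones. The camera test gave p = 2.5e-05 with the preset correlation and p = 0.057 with an estimated correlation, and the permutation over loci gave p = 8e-05. Among DROSHA-dependent miRNAs alone the medians were -0.67 (110 miRNAs) and -0.05 (37), a difference of -0.62 with p = 0.0073 (camera), p = 0.23 with an estimated correlation and p = 0.025 (permutation over loci). Per library, the mean log2 CPM of intronic miRNAs minus that of the others was -0.48 ± 0.16 with p140 and 0.35 ± 0.087 with full-length DROSHA, and an exact permutation test of the 3 against 3 libraries gave p = 0.1, the smallest it allows.

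Less conserved intronic miRNAs stood lower than broadly conserved ones, at a median of -0.74 against -0.38, but camera (p = 0.99) and the locus permutation (p = 0.71) found no difference over all of them. The medians and the tests thus differ. Among DROSHA-dependent intronic miRNAs the medians were -1.27 (40 less conserved) and -0.34 (70 broadly conserved), a difference of -0.93 with p = 3.6e-05 (camera) and 6e-05 (permutation over loci).

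No family list passed the camera test as a group. Of 19 let-7 members 9 fell and 0 rose (9 when adjusted over the list alone), with a median of -0.63 and adjusted p = 0.20 (camera). let-7i-5p fell by 0.73 ± 0.12, while let-7a-5p had a log2 fold change of 0.25 ± 0.13. The CLCN5 cluster, a group of X-linked intronic miRNAs, had 8 of 13 members lower (8 over the list alone), a median of -0.83 and adjusted p = 0.082 (camera), with miR-532-5p at -0.76 and miR-660-5p at -0.36. In the proliferation-linked miR-17/92 list 4 of 11 fell (4 over the list alone, median -0.55, camera adjusted p = 0.24), among them miR-19b-3p at -0.59, with miR-92a-3p at -0.19. In miR-15/16 4 of 11 fell (4 over the list alone, median -0.38, adjusted p = 0.63), led by miR-15b-5p (SMC4 intron) at -1.36, while miR-16-5p stood at 0.03. Of 7 HOX locus miRNAs 3 fell (2 over the list alone, median -0.58, adjusted p = 0.46), with miR-196b-5p at -0.79 and miR-10a-5p at -0.25. In the miR-200 list 1 of 4 fell (1 over the list alone, median -0.52, adjusted p = 0.71), miR-200c-3p at -1.01, and miR-141-3p stood at -0.70.

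The miR-106b/25 list had 1 of 6 lower (0 over the list alone, median -0.19, adjusted p = 0.92), with miR-25-3p at -0.54 and miR-93-5p at 0.32. The p53-linked list had 1 of 4 higher and 1 lower (the same over the list alone, median -0.18, adjusted p = 0.92), with miR-34a-5p at 0.53 and miR-34a-3p at -0.03; the former becomes -1.02 on the DROSHA-independent scale. In miR-23/27/24 1 of 10 rose (0 over the list alone, median 0.21 and -1.42 on the DROSHA-independent scale, adjusted p = 0.63), miR-24-3p at 0.30, which turns to -1.29 on the DROSHA-independent scale and to -0.01 without a count filter, while miR-27a-3p stood at 0.21. The miR-29/30 list had 2 higher and 2 lower of 17 (1 and 1 over the list alone), a median of 0.08 that turns negative with DESeq2 (-0.12), a mean just below 0 and adjusted p = 0.89, with miR-29a-3p at 0.00 and miR-29b-3p at 0.39. In miR-221 and miR-222 2 rose and 2 fell (2 and 2 over the list alone, median 0.02 and -0.19 with DESeq2, mean -0.08, adjusted p = 0.92). miR-222-3p rose by 0.44 ± 0.14 (-1.18 on the DROSHA-independent scale) and miR-221-3p fell by 0.38 ± 0.10. The hypoxia-linked miR-210-3p fell by 0.96 (1 of 1, also over the list alone). Neither of 2 miR-106a and miR-363 members passed (0 over the list alone), with miR-106a-5p at -0.17 and miR-18b-5p at -0.90. Of the markers of other cells, the muscle and neural list had 1 tested member, miR-219a-5p, which fell by 1.98 (1 over the list alone). The blood, DLK1-DIO3, C19MC and pluripotency lists had 0 members tested.

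**Figure D3:**
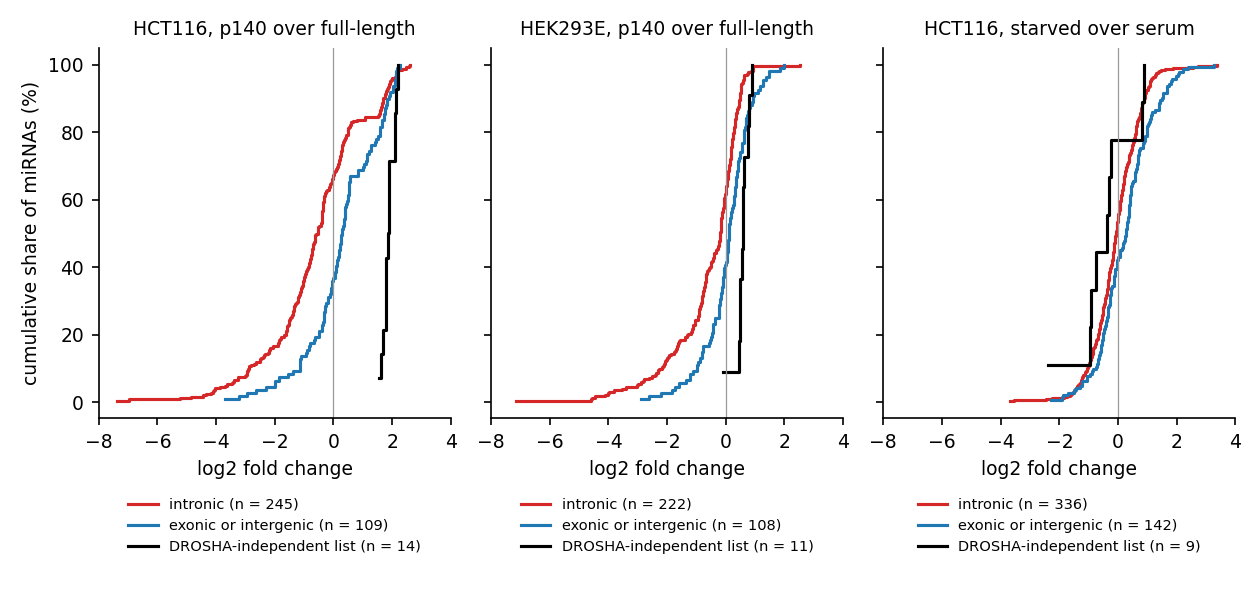
Cumulative share of miRNAs (percent) by log2 fold change for intronic miRNAs, exonic or intergenic miRNAs and the DROSHA-independent list in the 3 comparisons. The intronic curve lies left of the other class in each panel, by -0.83, -0.29 and -0.34 at the median, and the list rises furthest in HCT116 (median 1.87).

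The same exchange in HEK293E cells gave fewer and mostly downward calls on the main scale, again led by intronic miRNAs. On the DROSHA-independent scale the calls in HEK293E outnumbered those in HCT116. miR-1296-5p fell from 1241 ± 289 to 48.4 ± 22.9 CPM, by 4.58 ± 0.34 on the log2 scale. miR-941, a miRNA with tandem copies in an intron of DNAJC5 (chr20:63919495-63919517 for the copy used), went the other way, from 610.4 ± 151.8 to 3507 ± 679 CPM, and rose by 2.52 ± 0.23. miR-218-5p, which is among the most abundant miRNAs of these cells, fell by 0.79 ± 0.12 (73269 ± 6581 to 42433 ± 2776 CPM). Of 416 miRNAs tested 88 fell and 22 rose (edgeR's quasi-likelihood test), 64 and 11 by more than 2-fold, and 42.3% had groups without overlap against 10% by chance. With the replicate number as a block the calls were 113 falls and 70 rises, that is 61.7% falls in place of 88 falls and 22 rises.

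The 12 largest falls at a mean of at least 100 CPM without overlap between the groups were all intronic. After miR-1296-5p came miR-548b-3p (FAM184A) at -4.54, miR-1305 (TENM3) at -4.11, miR-576-5p (SEC24B) at -3.99, miR-3176 (CAPN15) at -3.55, miR-629-3p (TLE3) at -3.39 and miR-625-3p (FUT8) at -3.01. miR-374a-3p (FTX) had -3.001, miR-491-5p (FOCAD) -2.90, miR-629-5p -2.78, miR-577 (UGT8) -2.63 and miR-1301-3p (DNMT3A) -2.51. Adjusted p-values ran from 1.3e-05 for miR-1296-5p to 4.5e-04 for miR-491-5p (edgeR's quasi-likelihood test, Benjamini-Hochberg). The largest rises after miR-941 at a mean of at least 100 CPM without overlap between the groups were of miR-2110 at 1.84, miR-4517 at 1.52, miR-4787-3p at 1.48, miR-760 at 1.39, miR-3143 at 1.28, miR-4521 at 1.28 and miR-3144-3p at 1.17. miR-6724-5p had 0.95, miR-1254 0.85, miR-636 0.84 and miR-1292-5p (NOP56) 0.82. Adjusted p-values ran from 3.0e-05 for miR-941 to 0.040 for miR-1292-5p (edgeR's quasi-likelihood test, Benjamini-Hochberg).

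Of the DROSHA-independent list 3 of 11 members rose in HEK293E, at a list median of 0.57 (4 when adjusted over the list alone, 1 in the joint fit of all replicated libraries; camera adjusted p = 0.019 over 11 lists, and adjusted p = 0.80 with an estimated correlation). miR-877-5p rose by 0.81 ± 0.15, miR-320a by 0.77 ± 0.15 and miR-484 by 0.58 ± 0.17, and the last becomes -0.16 on the scale of its own list. That scale shifts the median of all miRNAs by -0.72 and makes 98.1% of calls falls. Intronic miRNAs had a median of -0.18 and the others 0.11, a difference of -0.29. Of the intronic ones 67 fell and 1 rose, and of the others 14 fell and 11 rose. The median of the others is -0.59 on the DROSHA-independent scale, with -0.89 for the intronic ones. The difference had p = 9.0e-05 (camera), p = 0.0089 with an estimated correlation and p = 0.0033 in the permutation over loci. Among DROSHA-dependent miRNAs it was -0.20, with p = 0.041 (camera), p = 0.16 with an estimated correlation and p = 0.22 (permutation over loci). The same difference per library was 0.16 ± 0.052 with p140 and 0.74 ± 0.014 with full-length DROSHA (exact permutation test of 3 against 3, p = 0.1, the smallest it allows).

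Less conserved intronic miRNAs were lower than broadly conserved ones in HEK293E, at -0.62 against -0.08 (camera p = 5.3e-04, p = 0.075 with an estimated correlation, p = 0.060 in the permutation over loci). Among DROSHA-dependent ones the medians were -0.94 and 0.03, a difference of -0.98 (camera p = 1.6e-09, permutation over loci p = 1e-05, the smallest possible).

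No family list passed the camera test in HEK293E. No let-7 member of 12 passed (0 over the list alone, median 0.29, -0.43 on the DROSHA-independent scale, camera adjusted p = 0.53), with let-7a-5p at 0.34 and let-7f-5p at 0.37. Of 11 miR-17/92 miRNAs 1 fell (1 over the list alone, median -0.17, adjusted p = 0.97), with miR-92a-3p at -0.01 and miR-19b-3p at -0.04. None passed, also over the list alone (0), in miR-106b/25 (6 tested, adjusted p = 0.58, miR-93-5p at 0.17 and miR-25-3p at 0.04), the p53-linked list (5, 0.77, miR-34a-5p at 0.31), miR-15/16 (12, 0.54, miR-16-5p at 0.03 and miR-15b-5p at 0.03) and miR-23/27/24 (6, 0.54, miR-27b-3p at 0.18). The same held for miR-29/30 (16, 0.54, miR-30d-5p at 0.19 and miR-30c-5p at 0.00) and miR-221 and miR-222 (4, 0.53, miR-222-3p at 0.36 and miR-221-3p at 0.30), and for the 2 members each of miR-106a and miR-363 and miR-200, for which camera was not run. On the DROSHA-independent scale miR-93-5p, miR-25-3p, miR-16-5p, miR-15b-5p, miR-30d-5p, miR-30c-5p and miR-10a-5p turn negative, and 9 of 11 miR-17/92, 8 of 12 miR-15/16, 5 of 6 miR-106b/25, 5 of 16 miR-29/30 and 4 of 12 let-7 members fell. In those 2 pairs miR-106a-5p stood at -0.13, miR-18b-5p at 0.47, miR-200c-3p at -0.83 and miR-141-3p at -0.10. Of 8 HOX locus miRNAs 3 fell (3 over the list alone, 6 on the DROSHA-independent scale, median -0.07 and 0.02 with RLE scaling, adjusted p = 0.54), with miR-196b-5p at -0.85 ± 0.15 and miR-10a-5p, one of the 5 most abundant, at 0.01. In the CLCN5 cluster 1 of 12 fell (1 over the list alone, 8 on the DROSHA-independent scale, median -0.35, adjusted p = 0.79), with miR-660-5p at 0.03 and miR-532-5p at 0.14. miR-210-3p stood at -0.89 (adjusted p = 0.096 with edgeR's quasi-likelihood test; 1 when adjusted over the list alone). Of markers of other cells, miR-486-5p of the blood list fell by 1.79 (1 of 1, also over the list alone), and miR-219a-5p of the muscle and neural list fell by 2.63 (1 of 2, also over the list alone), while miR-124-3p stood at -0.71. The DLK1-DIO3, C19MC and pluripotency lists had 0 members tested.

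The p140 effects of the 2 lines moved together. Over 350 miRNAs tested in both, the log2 fold changes had a Pearson r of 0.85 and a Spearman rho of 0.88 across miRNAs, which are not independent replicates. Of 120 falls in HCT116 and 73 in HEK293E, 68 were shared against 25.03 by chance (Fisher's exact test, p = 4.9e-33). Of 88 and 19 rises, 17 were shared against 4.78 by chance (Fisher's exact test, p = 2.0e-09). Of the 85 miRNAs called in both lines, 0 moved in opposite directions. Among the 68 shared falls 54 were intronic and 11 exonic or intergenic (Fisher's exact test against all tested in both, p = 0.0056). These Fisher's exact tests count both arms of a hairpin and members of a cluster as independent, so their p-values may be too small. The shared rises held 1 intronic and 9 exonic or intergenic miRNAs. The size of the effect differed between lines for 17 miRNAs in the interaction test, 11 of them higher and 6 lower in HEK293E. The number was 102 with the replicate block, 0 on the DROSHA-independent scale, and 5 to 85 with 1 library left out. miR-421 fell by 4.16 in HCT116 and by 1.69 in HEK293E, miR-454-3p by 2.87 and by 0.84, and miR-15b-5p by 1.36 in HCT116, with 0.03 in HEK293E.

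**Figure D4:**
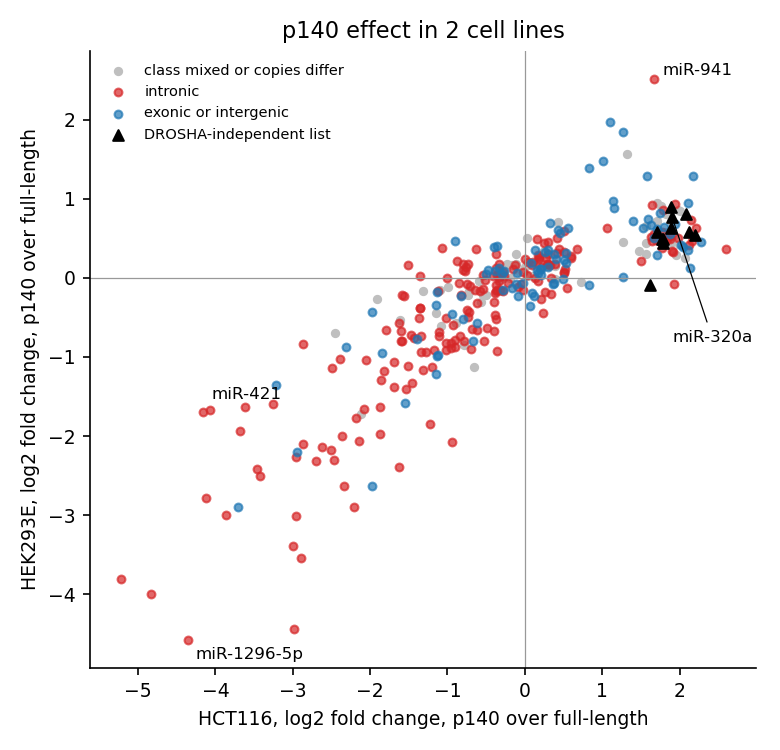
Log2 fold change of p140 over full-length DROSHA in HEK293E (vertical) against HCT116 (horizontal) for 350 miRNAs, 1 point each, coloured by class, with the DROSHA-independent list as triangles. Most falls shared by both lines are intronic (54 of 68), and miR-941 stands above the other rises in HEK293E.

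The last comparison asks what serum starvation does to miRNAs of wild-type HCT116 cells, with 3 libraries per condition. Of the miRNAs with a mean of at least 100 CPM and no overlap between the groups miR-95-3p rose most, from 28.4 ± 3.54 CPM in 9.1% FBS to 186.1 ± 7.004 in 0.1% FBS, by 2.71 ± 0.15 on the log2 scale. The p53 target miR-34a-5p (exonic in MIR34AHG, chr1:9151735-9151756) rose from 1393 ± 625.3 to 4447 ± 1049 CPM, by 1.67 ± 0.30. miR-194-5p rose by 2.04 ± 0.15, the growth-restraining miR-26a-5p by 1.31 ± 0.09 and the sterol-linked miR-33a-5p (SREBF2) by 1.62 ± 0.51. miR-4521 fell by 1.89 ± 0.23, from 1440 ± 334 to 388 ± 102 CPM. By edgeR's quasi-likelihood test 264 miRNAs changed, of which 117 fell, with 58 rises and 57 falls of more than 2-fold, and 54.9% had groups without overlap against 10% by chance.

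Further large rises were of miR-146b-5p at 1.403, miR-190a-5p (TLN2) at 1.39, miR-210-3p at 1.25, miR-151b at 1.14, miR-34a-3p at 1.14, miR-425-5p (DALRD3) at 1.10 and miR-125b-5p at 1.09. Adjusted p-values of the 12 ran from 1.7e-05 for miR-95-3p to 0.029 for miR-33a-5p (edgeR's quasi-likelihood test, Benjamini-Hochberg). The falls after miR-4521 were smaller. miR-335-3p (MEST) fell by 1.48 ± 0.13, miR-942-5p (TTF2) by 1.22, miR-15b-3p (SMC4) by 0.96, miR-421 by 0.79, miR-224-5p (GABRE) by 0.77 and miR-33b-3p (SREBF1) by 0.75. miR-1301-3p fell by 0.65, miR-15b-5p by 0.64, miR-19b-1-5p by 0.61, miR-550a-3p by 0.61 and miR-3200-3p (OSBP2) by 0.58. Adjusted p-values of the falls ran from 1.2e-04 for miR-335-3p to 0.016 for miR-19b-1-5p (edgeR's quasi-likelihood test, Benjamini-Hochberg). Of the most abundant miRNAs, miR-31-5p rose by 0.85, let-7a-5p by 0.71, miR-21-5p by 0.43 and miR-222-3p by 0.38, while miR-221-3p stood at 0.19 (adjusted p = 0.077). On the DROSHA-independent scale the median of all miRNAs shifts by -0.64, 91.7% of calls are falls in place of 44.3%, and miR-21-5p (-0.22) and miR-222-3p (-0.27) turn negative. That scale rests mostly on miR-320a, which held 1.13% of reads where the list held 1.26% (0.1% FBS, replicate 1). miR-320a itself rose by 0.82 on the main scale. The joint fit of all replicated libraries gives 57.8% falls.

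**Figure D5:**
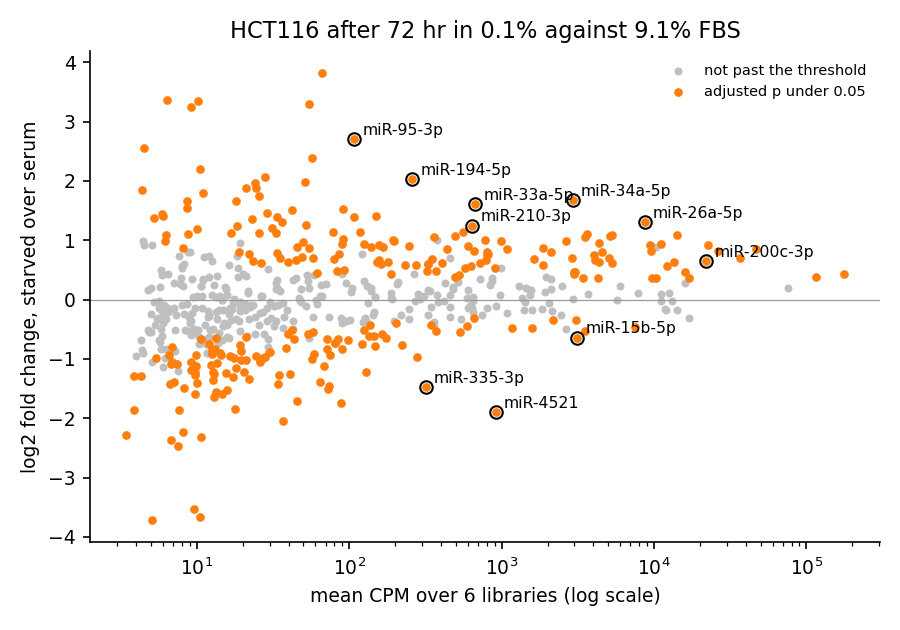
Log2 fold change after 72 hr in 0.1% against 9.1% FBS (vertical) by mean CPM over 6 libraries (horizontal, log scale), 1 point per miRNA, coloured where the adjusted p is under 0.05. miR-95-3p (2.71) and miR-4521 (-1.89) mark the largest rise and fall at a mean of at least 100 CPM without overlap between the groups.

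The p53-linked list rose as a group. All 5 tested members rose (5 over the list alone), with a median of 1.67, which stays positive under every scaling tried (lowest 1.01, on the DROSHA-independent scale). The camera test over 14 lists gave adjusted p = 9.5e-06, and adjusted p = 0.19 with an estimated correlation. Of the epithelial miR-200 list 7 of 9 rose (7 over the list alone, 1 in the joint fit and 0 on the DROSHA-independent scale), with a median of 0.63 that falls to just below 0 on the DROSHA-independent scale (camera adjusted p = 0.020, and adjusted p = 0.19 with an estimated correlation). miR-200c-3p rose by 0.65 and miR-141-3p by 0.63 on the main scale. The CLCN5 cluster had 5 of 14 members lower and 0 higher (5 over the list alone, 13 on the DROSHA-independent scale), a median of -0.36 and adjusted p = 0.025 (camera), and adjusted p = 0.26 with an estimated correlation, with miR-660-5p at -0.13 and miR-532-5p at -0.15. Of the blood list 4 of 5 rose (4 higher and 1 lower over the list alone), with a median of 1.98 (camera adjusted p = 0.0036, and adjusted p = 0.19 with an estimated correlation). miR-486-5p, best known from red blood cells, rose by 3.31 ± 0.24, miR-486-3p by 3.35, miR-142-3p, a miRNA of blood cells, by 1.98 and miR-142-5p by 1.75, while miR-150-5p stood at -0.90.

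The remaining lists did not pass as groups without a block. Of 19 let-7 members 10 rose (10 over the list alone, 5 in the joint fit, and 0 with 3 falls on the DROSHA-independent scale), with a median of 0.36 that turns to -0.28 on the DROSHA-independent scale (camera adjusted p = 0.064, and 0.014 with the replicate block, or 0.34 with the block and an estimated correlation). Of 12 miR-17/92 miRNAs 4 fell (3 over the list alone, median -0.35, adjusted p = 0.095, and 0.014 with the block, or 0.36 with the block and an estimated correlation), with miR-92a-3p at -0.31 and miR-19b-3p at -0.18. In miR-15/16 5 of 12 fell and 2 rose (5 and 2 over the list alone, median -0.43, adjusted p = 0.095, and 0.031 with the block, or 0.38 with the block and an estimated correlation), with miR-16-5p at -0.03. Of the DROSHA-independent list 2 of 9 rose and 3 fell (2 and 3 over the list alone, median -0.37, adjusted p = 0.28; 0 and 3 in the joint fit, and 0 and 6 with a median of -1.03 on its own scale, which thus does not centre the list). miR-320a rose by 0.82, with miR-484 at -0.23 and miR-877-5p at -0.37. miR-29/30 had 7 higher and 4 lower of 17 (9 and 5 over the list alone, median 0.36 and -0.27 on the DROSHA-independent scale, adjusted p = 0.59), with miR-29a-3p at 0.82 and miR-29b-3p at 0.88. In miR-23/27/24 4 of 11 rose (4 over the list alone, median 0.27 and -0.36 on the DROSHA-independent scale, adjusted p = 0.39), with miR-27a-3p at 0.47 and miR-23a-3p at 0.27. The HOX loci had 3 of 8 higher (3 over the list alone, median 0.44 and -0.20 on the DROSHA-independent scale, adjusted p = 0.21), with miR-10a-5p at 0.99 and miR-196b-5p at -0.17.

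The imprinted DLK1-DIO3 cluster had 2 of 22 lower (1 over the list alone, 12 on the DROSHA-independent scale, median -0.34, adjusted p = 0.095), with miR-376a-3p at -0.29 and miR-376c-3p at -0.09. In miR-106b/25 1 of 6 rose (1 over the list alone, adjusted p = 0.90), miR-25-3p at 0.36, which turns to -0.28 on the DROSHA-independent scale, and miR-93-5p stood at 0.10. In miR-221 and miR-222 1 rose and 1 fell of 4 (the same over the list alone, adjusted p = 0.98). Of the hypoxia list the 1 tested member, miR-210-3p, rose (1 over the list alone), and of the 2 tested in miR-106a and miR-363 (miR-106a-5p at -0.11 and miR-18b-5p at -0.05) and the 2 of the muscle and neural list (miR-219a-5p at 0.27 and miR-219a-1-3p at -0.25) none passed, also over the list alone (0). The C19MC and pluripotency lists had 0 members tested.

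Intronic miRNAs stood lower than the others after starvation as well, at a median of -0.07 against 0.27, a difference of -0.34. Of the intronic ones 78 rose and 72 fell, and of the others 49 rose and 21 fell. The median of the others is -0.37 on the DROSHA-independent scale, with -0.70 for the intronic ones. The difference had p = 0.015 (camera), p = 0.16 with an estimated correlation and p = 4.6e-04 (permutation over 190 and 83 loci), and was -0.12 with p = 0.23 (camera) among DROSHA-dependent miRNAs. The same difference per library was 0.083 ± 0.059 in 0.1% and 0.38 ± 0.022 in 9.1% FBS (exact permutation test of 3 against 3, p = 0.1, the smallest it allows). Less conserved intronic miRNAs had a median of -0.29 and broadly conserved ones 0.32 (camera p = 2.8e-06, p = 0.037 with an estimated correlation and 0.066 with that and the replicate block, permutation over loci p = 2e-05), while among DROSHA-dependent ones the difference was -0.22 (camera p = 0.14).

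Over 396 miRNAs the log2 fold changes of starvation and of p140 in HCT116 had a Pearson r of -0.01 and a Spearman rho of 0.03. Shared falls numbered 30 against 27.4 by chance and shared rises 24 against 24.3, and of the miRNAs called in both 51 moved in opposite directions. miR-374a-5p, which fell with p140, rose by 0.96 after starvation, and miR-4521, which rose with p140, fell by 1.89. Pearson r and Spearman rho were 0.18 and 0.23 for miRNAs with a mean of at least 100 CPM and 0.25 and 0.26 for DROSHA-dependent ones. Of the DROSHA-dependent miRNAs 10 rose in both against 5.47 by chance (Fisher's exact test, p = 0.016). Shared falls among them numbered 8 against 7.98 by chance, and 23 of the 41 called in both moved in opposite directions. Against p140 in HEK293E the Pearson r was 0.02 over 356 miRNAs, with 22 shared falls against 15.0 by chance (Fisher's exact test, p = 0.033). Shared rises there numbered 5 against 6.55 by chance, and 25 of the 52 called in both moved in opposite directions. Here too Fisher's exact test counts each mature miRNA as independent.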

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

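The tests of 1 library and of the scaling in this part were chosen only after the differences between the lines had been seen.

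A total of 17 miRNAs differed between HCT116 and HEK293E in their response to p140 by the interaction test, and those named by the rule follow as HEK293E minus HCT116 on the log2 scale. Of the FTX locus 3 miRNAs fell less in HEK293E, with a difference of 2.39 for miR-421, 1.90 for miR-374b-5p and 0.99 for miR-374a-5p. So did miR-454-3p (1.96). miR-15b-5p (1.31) and let-7f-5p (0.94) did not fall in HEK293E, where they stood at 0.03 and 0.37. miR-1260b (-1.67), miR-4286 (-1.79) and miR-484 (-1.17) rose less in HEK293E. Chosen after their values were seen, the others higher in HEK293E were miR-19a-3p (1.68), miR-98-5p (1.38), miR-425-5p (1.28), miR-30e-5p (0.91) and miR-181b-5p (0.85), and those lower were miR-1250-5p (-5.90), miR-4722-5p (-6.35) and miR-3188 (-2.05). The count filter of this fit can be passed in a single group of libraries. The largest differences may therefore rest on few reads in a line and need not be the strongest effects.

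The 11 miRNAs higher in HEK293E had a median difference of 1.31 and the 6 lower ones of -1.92. Replicate 3 of HCT116 with p140, which stood apart from its group, is not their source, since without it 17 of the 17 were called in the same direction (85 calls in all). Scaling to the DROSHA-independent list shifts all differences upward, at a median of 0.97, so by construction it raised the median of the 11 to 2.13 (median standard error 0.83) and brought that of the 6 to -0.79 (0.67). On that scale edgeR called 0, and 11 of the 11 and 2 of the 6 kept an unadjusted p under 0.05. Of the 6, miR-484, miR-1260b and miR-4286 shrank to -0.07, -0.60 and -0.62 on that scale. The scaling may thus account for much of these, though miR-484, a member of the list, is drawn towards 0 partly by construction. miR-3188 stood at -0.96, and miR-1250-5p and miR-4722-5p at -4.96 and -4.88. Whether the scaling or what DROSHA-p140 processes in each line is behind the other differences stays open.

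For the numbers of changed miRNAs, 1 of the 10 splits of the 6 HCT116 libraries into 3 and 3, the real one, gave 266 calls, and the highest of the others gave 0. In HEK293E the real split gave 110 and in the serum experiment 264, again 1 split of 10 each, with 0 as the highest of the others. Among the 4 splits that part all 3 replicate pairs the highest other was 0 as well. With 10 splits no share under 0.05 can be had.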

How the results depend on the processing

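The estimated correlation of the conservation comparison, the restriction to DROSHA-dependent miRNAs and DROSHA-independent scaling of the interaction were chosen after the data were seen, and the causes of the changes given here were not tested unless stated. The 12 main results had 140 values under alternatives, of which 111 kept direction and side of the threshold, or stayed within 1.5 times for counts. The 164 results for single miRNAs had 2496 values, of which 2261 kept both, 81 gained a call, 20 reversed and the others lost it. Of these 20, 19 reversed on the DROSHA-independent scale, which rests mostly on the reads of miR-320a. In HCT116 they were miR-484 (-0.091), miR-34a-5p (-1.02), miR-24-3p (-1.29) and miR-222-3p (-1.18). In HEK293E they were miR-484 (-0.16), miR-93-5p (-0.54), miR-25-3p (-0.69), miR-16-5p (-0.67), miR-15b-5p (-0.69), miR-30d-5p (-0.53), miR-30c-5p (-0.71) and miR-10a-5p (-0.71). After starvation they were let-7f-5p (-0.28), miR-25-3p (-0.28), miR-200c-3p (-0.0044), miR-141-3p (-0.0045), miR-27a-3p (-0.17), miR-222-3p (-0.27) and miR-21-5p (-0.22). The other was miR-24-3p in HCT116 without a count filter (-0.0078).

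On the DROSHA-independent scale the calls numbered 170 in HCT116 and 2.2e+02 in HEK293E. With a mean of at least 100 CPM, where fewer miRNAs are tested, they numbered 1.4e+02 in HCT116 and 112 after starvation. The replicate block gave 1.8e+02 calls in HEK293E, 3.3e+02 in HCT116 and 3.7e+02 after starvation, and changed no other call of a main result or list than those given in the report. The shift of the median of all miRNAs exceeded 0.1 also with RLE (0.10), DESeq2 (-0.20), no count filter (-0.30), a mean of at least 100 CPM (0.17), and without replicate 3 of p140 (-0.11) or of full-length DROSHA (-0.12) in HCT116, and with the joint fit (-0.18) and a mean of at least 100 CPM (-0.18) after starvation. The difference between intronic and other miRNAs kept its sign throughout. It lost its call in HCT116 with an estimated correlation (-0.83, p = 0.057). After starvation it did so without a count filter (-0.16, p = 0.065), at a mean of at least 100 CPM (-0.23, p = 0.062), with 1 arm per hairpin (-0.36, p = 0.063), with an estimated correlation (-0.34, p = 0.16) and for DROSHA-dependent miRNAs (-0.12, p = 0.23). The conservation difference in HCT116 gained a call with the hand-made class list (-0.90, p = 6.2e-05) and for DROSHA-dependent miRNAs (-0.93, p = 3.6e-05), and that in HEK293E lost it with an estimated correlation (-0.54, p = 0.075). The correlation of the lines was 0.89 for DROSHA-dependent miRNAs. That of HCT116 p140 with starvation turned positive at a mean of at least 100 CPM (0.18) and for DROSHA-dependent miRNAs (0.25).

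The interaction was the least stable result, with 17 calls on the main scale, 11 with RLE, 0 on the DROSHA-independent scale, 22 with DESeq2 and 102 with the replicate block. With 1 library left out it ranged from 5 (without HEK293E p140 replicate 2) to 85 (without HCT116 p140 replicate 3). It was 8 and 6 without HCT116 p140 replicates 1 and 2, 7 without any one full-length HCT116 library, and 11 and 7 without HEK293E p140 replicates 1 and 3. With 1 library left out the other results ranged from 1.8e+02 to 388 calls in HCT116, 86 to 1.3e+02 in HEK293E and 2.1e+02 to 281 after starvation. The intronic difference ranged from -0.93 to -0.80, -0.41 to -0.34 and -0.40 to -0.26 in the same order, and the difference in DROSHA-independent share in HCT116 from 8.89 to 15.9 percentage points. Without replicate 3 of both HCT116 groups 366 miRNAs were called and the intronic difference was -0.83. Of 984 values for single miRNAs with 1 library left out, 914 kept their call, 55 lost it, 15 gained it and 0 reversed. Depth limits the knockout with GFP most, where 38288 reads bound a miRNA at 0 reads no further than the folds given. In simulation each design missed most 1.5-fold changes, whatever its depth. Scaling to spike-in RNAs was not run, as the tables hold none.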

Other observations

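The tests of the miR-200 reads and levels were chosen only after the values had been seen.

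The miR-200 family, which maintains epithelial character, was nearly absent from the rescued HCT116 knockout cells. miR-200c-3p had 25988 CPM in untreated wild type and 19727 ± 2208 in the wild-type cells in 9.1% FBS, but 180.3 ± 24.7 with full-length DROSHA and 94.0 ± 12.5 with p140 (unscaled CPM, n = 3 each where an SD is given). The 8 members among the DROSHA-dependent miRNAs had a median log2 ratio of full-length rescue to wild type of -7.13, or 140-fold lower, while the median over all was 0.24. An incomplete rescue shared evenly by all miRNAs is argued against as the cause of this low level. The list stood at percentile 0 of random matched lists, whose medians lay between -0.49 and 0.62. The random lists treat arms and cluster members as independent. CPM is relative to the library total, so these ratios cannot tell whether the rescue as a whole was complete. The DROSHA-independent share was 4.09% with full-length DROSHA and 1.27% in untreated wild type. All 8 were among the 12 DROSHA-dependent miRNAs that were over 8-fold lower, with miR-375 (43.7-fold), miR-135b-5p (17.4-fold), miR-9-5p (10.3-fold) and miR-9-3p (9.28-fold) as the others. In the other direction miR-301a-3p was 5.34-fold higher with full-length DROSHA than in wild type, miR-196b-5p 3.08-fold and miR-10a-5p 2.61-fold. The knockout with GFP had 2664 CPM of miR-200c-3p (102 reads), more than the rescued cells. The untreated wild type and the knockout with GFP are 1 library each.

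The rises with p140 in HCT116 formed a narrow group. Of 115 miRNAs that rose more than 2-fold, those outside the DROSHA-independent list had a median of 1.81 (SD 0.31), and 79 of them lay within the list's own range of 1.56 to 2.21. Only 19 miRNAs tested had a log2 fold change between 0.7 and 1.4, against 104 between 1.4 and 2.4. Outside the list 66 had at least 10 reads in knockout and wild type together. Their median log2 ratio of knockout to wild type on the list's scale was 0.47, against -7.55 for 97 that fell. A miRNA with few wild-type reads passed only through knockout reads, so the filter itself favours a high median among the 66. Of those with at least 100 wild-type reads, miR-4521, miR-320b, miR-3615, miR-320c and miR-1260b lay between -0.45 and 0.42, and miR-145-5p at -8.71. Some may thus be made without DROSHA although they were not listed. On the same scale 5 of the 66 were over 16-fold lower in the knockout, namely miR-941, miR-2110, miR-4787-3p, miR-5001-3p and miR-145-5p. The first 4 rose with p140 in both lines, by 1.68 and 2.52 for miR-941, 1.27 and 1.84 for miR-2110, 1.01 and 1.48 for miR-4787-3p, and 1.10 and 1.97 for miR-5001-3p, in HCT116 and HEK293E. They rest on 0 or 1 reads each in the knockout with GFP, against 26 to 85 in wild type.

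The lower intronic miRNAs with p140 were set against technical sources in a linear model over loci, where the intronic coefficient was -1.07 ± 0.25 in HCT116 and -0.77 ± 0.18 in HEK293E. It stayed at -0.78 and -0.66 with GC content of the mature sequence in the model, and at -1.06 and -0.82 with abundance. These values argue against either as the whole cause, though with GC only 73.4% of the coefficient was kept in HCT116. In a separate model of HCT116 without full-length replicate 1, the coefficient went from -0.98 to -0.89 (91.3% kept). Added there was the log2 ratio of full-length replicate 1 to untreated wild type. That ratio does not measure how active p140 was, so it cannot tell whether a weaker rescue by p140 lowered intronic miRNAs. Thinning all libraries to the shallowest left the difference of medians at -0.83 and -0.25. The 5p and 3p arms of a hairpin changed together (r = 0.96 over 98 hairpins and 0.92 over 87, against upper bounds of 0.25 and 0.29 after shuffling). The changes were thus shared by both arms, not particular to single mature strands. Both arms come from the same transcript, so this does not place the change at the cutting of the hairpin.

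Among intronic loci the log2 fold change was lower in longer host introns, with a Spearman rho of -0.47 in HCT116 and -0.38 in HEK293E (permutation p = 1e-05 each, the smallest possible). In HCT116 this trend includes loci in short introns that rose. Loci in 3 groups of rising intron length in HCT116 had median introns of 563, 6351 and 35932.5 bp and median log2 fold changes of 1.56, -0.71 and -1.09, and in HEK293E the medians were 0.02, -0.17 and -0.54. The coefficient per 10-fold intron length was -1.06 ± 0.16 in HCT116 and stayed at -0.87 with GC and -1.08 with conservation in the model. In HEK293E it was -0.52 ± 0.14, with -0.46 and -0.53. These models used all intronic loci, so they do not part a length effect from the rises in short introns. Mirtron-like hairpins in short introns may account for part of the trend. Among DROSHA-dependent loci rho was -0.28 (75 loci, permutation p = 0.015) in HCT116 and -0.23 (70 loci, p = 0.054) in HEK293E. A length effect and such hairpins cannot be told apart here. Hairpins standing alone did not differ from clustered ones in HCT116 (-0.017, permutation p = 0.97), while in HEK293E (-0.22, p = 0.34) that stays open.

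The knockout with GFP kept 5424 reads of DROSHA-dependent miRNAs, 14.2% of its total, with levels that followed wild type (r = 0.967 of log2 reads over 69 miRNAs with at least 10). Reads of HEK293E libraries are argued against, as the 5 miRNAs high in HEK293E had 59 reads where 782 would be needed, and 58 of the 59 were miR-4286. Reads of rescued knockout cells are argued against by the miR-200 family, with 190 reads (164 to 219.02) where the full-length composition gives 1.86. Wild-type composition gives 267, of which 190 is 71.1%, so the interval lies below this number too, though much nearer to it. Wild-type cells or wild-type library carry-over stay open, as do knockout cells that keep a trace of DROSHA activity and the miR-200 transcripts. The labels do not say whether this knockout population is the one that was rescued.

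After starvation, RNA carried in with the serum would lower blood miRNAs in 0.1% FBS. The median of that list was 1.98, with 5 of 13 members tested. The 4 that rose, both arms of miR-486 and of miR-142, argue against serum as their source. The other, miR-150-5p, stood at -0.90, and all 5 stayed below 100 CPM (85.7 ± 20.4 for miR-486-5p). A p140-like change is left open by the intronic difference of -0.34, which was lost with an estimated correlation. The relation to host intron length seen with p140 was not found over all loci after starvation (rho -0.077 over 190 loci, permutation p = 0.29). Among 75 DROSHA-dependent loci rho was -0.10, without a test, against -0.28 with p140 in HCT116. A weaker relation among those loci thus stays open.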
